A study of Mus musculus with 44 samples.

How the data were processed

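RNA of the hypothalamus (23 arrays) and of the remaining brain without hypothalamus (21 arrays) of adult male C57/Bl6 mice was measured on 44 dual-colour microarrays. Per the labels, total RNA was extracted from both tissues of each animal, the tissue RNA was labelled with Cy5, and a commercial universal mouse reference RNA was labelled with Cy3 on every array. No array carried the dyes the other way round, so a dye effect common to all arrays is part of every ratio and leaves the differences between groups. The groups were taken from the labels as untreated control, ACTH, ACTH gratified, furosemide and furosemide gratified. Group sizes in that order were 4, 5, 6, 4 and 4 arrays for the hypothalamus and 4, 4, 5, 4 and 4 arrays for the brain. No label states which arrays share an animal or were processed together, so tissues were compared unpaired and the p-values measure the spread between these samples. Scanner files were not used here.

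The deposited table holds 9554 features on 44 arrays with no missing value, from -2.65 to 3.17, and was taken as log2 ratios of tissue over reference made by the authors. Per the submitters' processing notes, limma was used; its version, the background correction, the normalization, the filtering of spots and the base of the logarithm are not given in the sources used here. Log base 2 was assumed, as limma's log ratios have it. Array medians ranged from -0.24 to -0.05, so the arrays were not centred on their own median, and whether features or arrays were centred in another way stays unknown. The direction of the ratio was checked on a pair of gene lists: the median over all features of the neuron list lay between 1.36 and 2.10 and that of the proliferation list between -1.77 and -1.11, with neuron above proliferation on 44 of 44 arrays. Values tied exactly with another feature on the same array made up 2.75 to 33.5% of an array's values, which is how a floor for weak spots would appear. Signal over background was not analysed here, and the number of arrays limits the precision.

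Features are named in the table by a gene symbol in capitals with the suffix gs, or g-s and a number where a gene has several. Of the 9554 names, 8651 matched a mouse symbol of the reference table, 580 matched 1 synonym, 29 matched several synonyms and 294 matched none. The matched features stand for 8097 symbols, of which 923 have more than 1 feature. The text uses the mouse symbol, adds the feature name where a gene has several features, and names no gene for a feature that matched several or none. Columns of per-sample values that could not be tied to a sample numbered 0.

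The numbers that end the sample descriptions fall into 3 series, here called the high-number series (3 digits beginning with 4), the 2-digit series and the zero-padded series. The high-number series holds all 20 ACTH and ACTH gratified arrays and no others. The 2-digit series holds 13 arrays and the zero-padded series 11. Hypothalamus controls and furosemide arrays are in the 2-digit series, and brain controls and furosemide arrays in the zero-padded series. Of the furosemide gratified arrays, hypothalamus replicates 1 and 2 and brain replicate 1 are zero-padded, and the others have 2 digits. The meaning of the series is not given in the sources used here. Tied values made up 20.3 to 33.5% of each high-number array, 2.81 to 14.9% of each 2-digit array and 2.75 to 16.1% of each zero-padded array.

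Differences between groups were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend or robust option), with group means only and no covariate. All hypothalamus arrays made 1 fit and all brain arrays another, so that the groups of a tissue shared an estimate of the spread; comparisons between tissues used 1 fit of all 44 arrays. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the 9554 features of a comparison, with 0.05 as the threshold and no minimum fold change. A feature past the threshold is said to have risen or fallen, and is called higher or lower between tissues. Fold changes are 2 raised to the difference between the group means of the log2 values, errors are standard errors of the fit unless SD is stated, and n counts arrays. No size is given for features tied on more than a share of 0.5 of the arrays of a compared group, except Hnrnpul1 and Rlbp1 for the tissue difference.

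Gene lists were tested with limma's camera on the moderated statistics, with the correlation between genes preset to 0.01, and adjusted over the 29 lists of a comparison. Each list result is given beside the adjusted p with a correlation estimated from the residuals. For each list, the number of members past the threshold is given over all features and adjusted over the list alone. A gene with several features entered by the feature with the largest SD over the arrays of the tissue. The 29 lists were dopamine and DARPP-32 signalling, immediate early genes, hypothalamic neuropeptides, glucocorticoid-responsive genes, renin-angiotensin, corticosteroid and natriuretic peptide systems, sodium channels and sodium-coupled transporters, opioid and cannabinoid signalling, glutamate receptors and postsynaptic density, GABA synthesis, transport and receptors, MAPK and CREB signalling, proteasome, oxidative phosphorylation, cytosolic ribosomal proteins, heat shock and endoplasmic reticulum stress, circadian clock, neuron, proliferation, astrocyte, oligodendrocyte and myelin, microglia and macrophage, endothelium and mural cells, choroid plexus and ependyma, blood, pituitary, striatum, cortex and hippocampus, thalamus and habenula, preoptic and hypothalamic regional markers, and cerebellum.

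The groups, the tests, the lists and the rule for naming genes were fixed before the data were examined. The rule took, per comparison, the 8 largest rises and the 8 largest falls among features with 1 symbol past the threshold, the 2 members of each list with the smallest adjusted p, and in the hypothalamus Ppp1r1b, Cartpt, Hcrt, Arc, Fos and Fkbp5. Where fewer than 5 features passed, the 4 rises and 4 falls with the smallest unadjusted p were taken and are said not to pass. A gene has 1 feature under the rule, that with the smallest p. Not every gene taken is printed, and some are not reported here. OR2A5gs and C20orf57g-s2, features without a mouse symbol, fall outside the rule and were chosen after their values were seen.

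Alternatives were array medians set to 0, quantile normalization, array weights, a trended and robust variance, only the groups of a comparison in the fit, the replicate number as a block, the number series as a factor or 1 series alone, other set tests, the mean of all features of a gene, and each array left out in turn. Leaving out features tied on more than a share of 0.5 of the arrays was added after seeing the data, as were the list tests with the block, the number series or 1 array left out, the pairing of arrays with neighbouring numbers across tissues and the use of ACTH and ACTH gratified arrays to compare the tissues. Comparisons sharing control arrays were set against 100 simulations of unchanged groups and against split controls. For each comparison, at most 100 splits of its arrays were drawn.

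The fit was tested on simulated data with 200 of 9554 features changed. For ACTH against control in the hypothalamus it recovered 10% of 50 features changed by a log2 of 0.25, 82% at 0.5, 96% at 1 and 100% at 2, with 11 false calls. For furosemide against control in the hypothalamus the shares were 8, 70, 94 and 100%, with 7 false calls. For furosemide against control in the brain they were 4, 72, 92 and 100%, with 4 false calls. Tables were prepared in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.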

Results

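The series measured gene expression in the hypothalamus and in the rest of the brain of mice under treatments that raise the drive for salt, and after that drive was gratified. ACTH is the pituitary hormone that stimulates the adrenal cortex, and furosemide is a diuretic that makes the kidney lose sodium. Each tissue had untreated controls, ACTH and furosemide groups, and for each treatment a gratified group, with 4 to 6 arrays per group and 44 arrays in all. Values are log2 ratios of tissue RNA over a common reference RNA for 9554 features. Within groups, the mean correlation of an array with the others of its group ranged from 0.77 to 0.975.

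**Figure D1:**
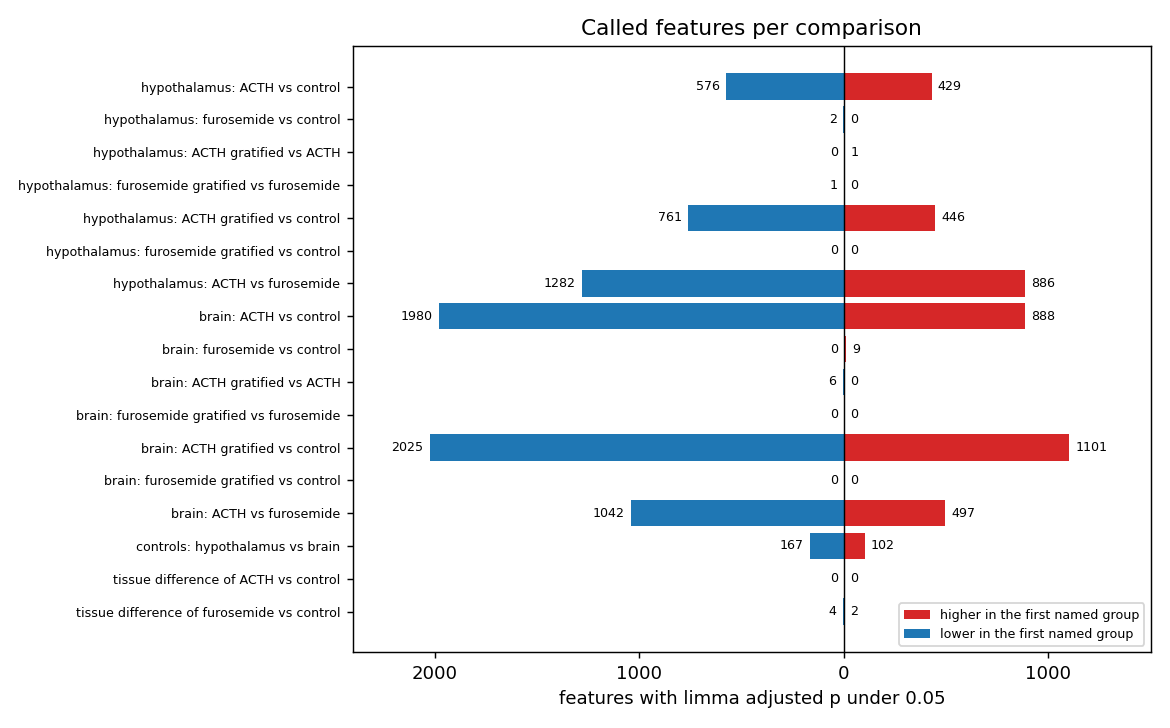
Number of features past an adjusted p of 0.05 in each comparison, higher to the right and lower to the left of 0, by tissue. Comparisons of ACTH or ACTH gratified arrays with control or furosemide arrays gave 1005 to 3126 features, and the gratification and furosemide comparisons with controls 0 to 9.

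Untreated controls were compared between the tissues. Hypothalamic peptide genes were the most different: Oxt, which encodes oxytocin, was 6.32-fold higher in hypothalamus than in the rest of the brain (log2 2.66 ± 0.28, n = 4 and 4, limma adjusted p = 3.75e-08). Avp, which encodes vasopressin, was 5.61-fold higher (log2 2.49 ± 0.25). Pmch, the precursor of melanin-concentrating hormone, and Hcrt, the precursor of the orexins, were 5.04-fold and 4.96-fold higher. Of 28 measured hypothalamic neuropeptides, 14 were higher and 1 lower over all features (15 and 4 adjusted over the list alone), with a median log2 difference of 0.39 (camera adjusted p = 5.52e-23, adjusted p = 0.0015 with an estimated correlation). The lower one over all features was Vip (log2 -0.99 ± 0.22), the precursor of vasoactive intestinal peptide, which is also made by cortical interneurons. Among 16 preoptic and hypothalamic regional markers, 7 were higher (10 over the list alone), including the transcription factor Nkx2-1 (1.67-fold), with a median of 0.43 (adjusted p = 1.35e-16, adjusted p = 0.000294 by estimated correlation). Thalamus and habenula markers were higher too, 7 of 11 (8 over the list alone), led by Tcf7l2 (feature TCF7L2g-s2, log2 1.24 ± 0.18) and Prkcd (log2 1.21 ± 0.27). The list median was 0.72 (adjusted p = 1.14e-16, adjusted p = 0.000294 by estimated correlation). The pituitary list had 2 of 8 members higher (4 over the list alone), including Pomc (log2 0.78 ± 0.13), the precursor of ACTH and melanocortins. Its median stood at 0.28 (adjusted p = 3.42e-05, adjusted p = 0.0257 by estimated correlation).

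Of 21 cortex and hippocampus markers 6 were lower in the hypothalamus (13 over the list alone), among them the transcription factors Mef2c (log2 -1.35 ± 0.28) and Neurod2 (log2 -1.22 ± 0.18). For the list, the median was -0.47 (adjusted p = 1.84e-11, adjusted p = 0.0717 by estimated correlation). Immediate early genes, transcribed within minutes of neuronal activity, were lower for 4 of 26 (9 over the list alone), including Egr1 (log2 -0.79 ± 0.14). The median over its members was -0.18 (adjusted p = 6.15e-06, adjusted p = 0.0744 by estimated correlation). In the oligodendrocyte and myelin list 1 of 17 was higher, Cldn11 (log2 0.99 ± 0.19), and 3 over the list alone (median 0.25, adjusted p = 3.96e-07, adjusted p = 0.082 by estimated correlation). In all, 269 features differed, 102 higher and 167 lower in hypothalamus. The controls of the tissues are in different number series. With the series as a factor 34 features passed, while Mef2c (adjusted p = 0.67), Prkcd (adjusted p = 0.11), Egr1 (adjusted p = 0.14), Vip (adjusted p = 0.45) and Cldn11 (adjusted p = 0.43) did not. The count was 624 with array weights and 169 to 171 without brain control replicate 3 or 4 or hypothalamus control replicate 2. In the ACTH and ACTH gratified arrays Tcf7l2, Cldn11, Vip and Egr1 did not differ (adjusted p = 0.87, 0.87, 0.17 and 0.051).

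ACTH was compared with control in the hypothalamus. Glul, glutamine synthetase of astrocytes, fell by 1.88 ± 0.11 on the log2 scale (3.69-fold, n = 5 against 4, limma adjusted p = 1.73e-10), and Fabp7, the fatty acid-binding protein of astroglia, fell by 0.91 ± 0.11. Atp1b3, a beta subunit of the sodium pump, fell by 0.51 ± 0.08 (adjusted p = 0.000728). The neuronal adhesion protein Cntn1 fell by 1.10 ± 0.27 and the synaptic vesicle protein Syn2 (feature SYN2g-s2) by 0.98 ± 0.21. Rbbp4, a histone-binding protein, rose by a log2 of 1.08 ± 0.15. The actin-binding protein gene Tagln2 (adjusted p = 2.36e-15), the protease inhibitor gene Serpinb13 and the cytokine gene Il17f passed as well, but their values are tied with other features on 5, 3 and 4 of the 5 ACTH arrays, so the size of these rises is not given.

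By group, the oligodendrocyte and myelin list fell for 4 of 17 members (9 over the list alone), with Opalin, an oligodendrocyte membrane protein, at -1.20 ± 0.16 and Car2, carbonic anhydrase, at -0.52 ± 0.11. Members had a median of -0.27 (adjusted p = 0.000731, adjusted p = 0.733 by estimated correlation). In the oxidative phosphorylation list 4 of 44 fell (6 over the list alone), for example Sdhb of succinate dehydrogenase (log2 -0.35 ± 0.09). As a list, the median was -0.25 (adjusted p = 0.000731, adjusted p = 0.773 by estimated correlation). In the proteasome list Psmd7 was the 1 of 27 that fell, by 0.42 ± 0.07, over all features and over the list alone (median -0.24, adjusted p = 0.006, adjusted p = 0.773 by estimated correlation). Thalamus and habenula markers fell for 5 of 11 (6 over the list alone), among them Tcf7l2 (feature TCF7L2g-s4, log2 -0.47 ± 0.12). Over its members, the median was -0.34 (adjusted p = 0.0036, adjusted p = 0.733 by estimated correlation). The microglia and macrophage list was not called (median -0.14, adjusted p = 0.241), but the microglial receptors Cx3cr1 and Trem2 fell by 0.66 ± 0.12 and 0.37 ± 0.08. Of the glucocorticoid-responsive genes 2 of 18 rose and 1, Glul, fell, the same numbers over the list alone (median 0.08, adjusted p = 0.651). Lcn2, a siderophore-binding protein, rose by a log2 of 0.66 ± 0.14 and Fkbp5, a chaperone of the glucocorticoid receptor, stood at 0.03 ± 0.15 (adjusted p = 0.906). Among 26 immediate early genes 1 rose and 2 fell, also over the list alone (median 0.08, adjusted p = 0.329): Ier2 rose by a log2 of 0.60 ± 0.07 and Jund fell by 0.29 ± 0.07. The differences of Fos (log2 0.18 ± 0.07, adjusted p = 0.0979), Arc (log2 0.23 ± 0.13, adjusted p = 0.264), Ppp1r1b, which encodes DARPP-32 (log2 0.24 ± 0.10, adjusted p = 0.13), Cartpt (log2 -0.20 ± 0.18, adjusted p = 0.476) and Hcrt (log2 -0.24 ± 0.27, adjusted p = 0.591) did not pass.

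In all, 1005 features changed, of which 576 fell. Every ACTH array is in the high-number series and no control array is, so series and treatment cannot be told apart. Of the rises 53.1% and of the falls 1.39% are features tied on most of the high-number arrays. The count was 514, 592 and 522 without hypothalamus control replicates 1, 2 and 3, 2753 with array weights and 1698 with only the groups compared. The oligodendrocyte and myelin call was lost under quantile normalization (median -0.13, adjusted p = 0.12), under which Fos (adjusted p = 0.045) and Ppp1r1b (adjusted p = 0.045) passed.

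**Figure D2:**
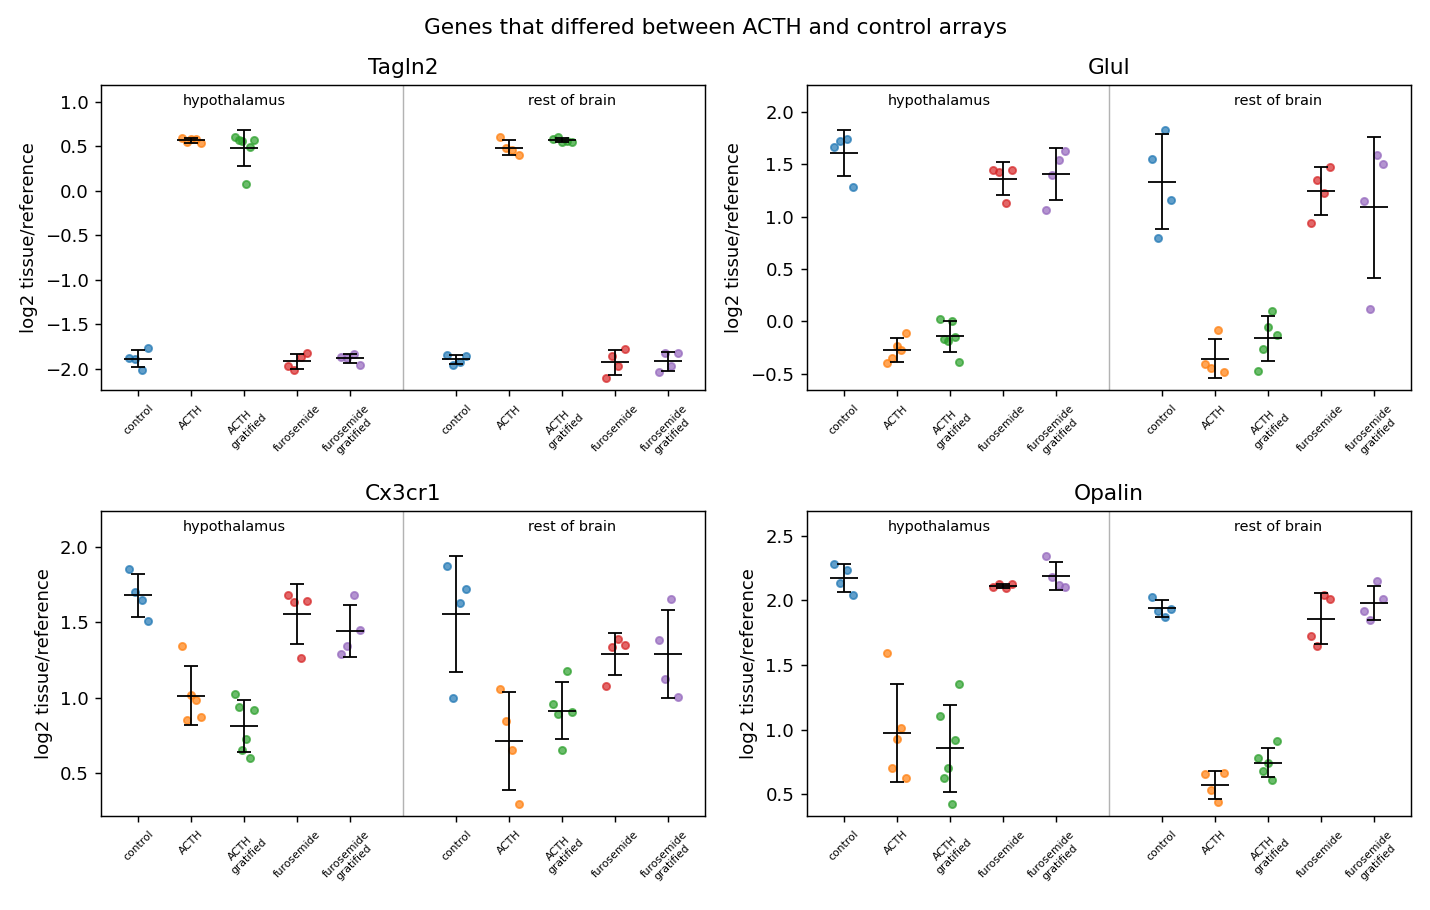
Log2 ratio of tissue over reference RNA for Tagln2, Glul, Cx3cr1 and Opalin in the 10 groups. Points are arrays, bars the group means and error bars the SD. Glul means lay between -0.36 and -0.14 in the ACTH and ACTH gratified groups of both tissues and between 1.09 and 1.61 in the other groups. Tagln2 values are tied with other features on 18 of the 20 ACTH and ACTH gratified arrays.

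The same comparison in the rest of the brain gave more changed features. Glul fell by 1.69 ± 0.25 on the log2 scale (3.23-fold, n = 4 and 4, limma adjusted p = 0.000184), and Atp1b3 by 0.76 ± 0.10. Opalin passed as a fall (adjusted p = 1.48e-08), and Tagln2 (adjusted p = 4.58e-15) and the surface protein gene Msln as rises, but they are tied with other features on 3, 4 and 4 of the 4 ACTH arrays, so no size is given. Alcam, an adhesion molecule, and Synpr, a synaptic vesicle protein (feature SYNPRg-s2), fell by 1.17 ± 0.18 and 1.22 ± 0.26.

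Genes of mitochondrial respiration fell together: 34 of 44 oxidative phosphorylation members fell (38 over the list alone), including Atp5b of the ATP synthase (log2 -0.82 ± 0.12) and Cox8a of cytochrome oxidase (log2 -0.76 ± 0.10). The median member stood at -0.40 (adjusted p = 9.91e-09, adjusted p = 0.982 by estimated correlation). Of 27 proteasome members 16 fell (17 over the list alone), with Psmc3 at -0.69 ± 0.09 and Psmb5 at -0.55 ± 0.09. The list had a median of -0.33 (adjusted p = 1.43e-05, adjusted p = 0.982 by estimated correlation). In the microglia and macrophage list 10 of 14 fell, also over the list alone (median -0.50, adjusted p = 0.0047, adjusted p = 0.982 by estimated correlation), among them Cx3cr1 (log2 -0.84 ± 0.18) and Trem2 (log2 -0.77 ± 0.09). Sodium channels and sodium-coupled transporters had 1 rise and 5 falls among 20, also over the list alone, and the list was not called (median -0.06, adjusted p = 0.85). Glucocorticoid-responsive genes, counted by 1 feature each, had 1 fall among 18, also over the list alone (median 0.02, adjusted p = 0.808). A rise in another feature of a gene would not show there. In all, 888 features rose and 1980 fell, 2868 in sum and 1895 without brain control replicate 3. As in the hypothalamus, treatment and series cannot be told apart, and 56% of the rises against 1.82% of the falls are features tied on most of the high-number arrays.

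Across features, the ACTH effects of the tissues correlated with r = 0.71. Features are not independent replicates. Among the called features 214 rose and 400 fell in both tissues, where independent lists would share 39.9 and 119, and 1 went opposite ways. A test of the difference itself called 0 features with limma (680 at an unadjusted p under 0.05). The smallest p belonged to Tcf7l2 (feature TCF7L2g-s2, adjusted p = 0.111), tied on 4 of 4 brain ACTH arrays, and Rbp4, a retinol carrier, stood 0.64 ± 0.14 higher in hypothalamus relative to brain (adjusted p = 0.137). The microglia and macrophage list was less reduced in the hypothalamus, with 14 of 14 members above 0 (median difference 0.31, 0 over all features and 1 over the list alone, adjusted p = 0.0016, adjusted p = 0.432 by estimated correlation). Thalamus and habenula markers went the other way (median -0.32, 0 members over all features and 0 over the list alone, adjusted p = 0.0122, adjusted p = 0.432 by estimated correlation). That call was lost under quantile normalization (adjusted p = 0.079), with the number series as a factor (adjusted p = 0.097), without brain control replicate 3 (adjusted p = 0.055), hypothalamus control replicate 3 (adjusted p = 0.051) and hypothalamus ACTH replicate 2 (adjusted p = 0.053). Without brain control replicate 1 or hypothalamus ACTH replicate 1, 2 features passed: Tcf7l2 at adjusted p = 0.0023 and 0.042, and Rbp4 at adjusted p = 0.042 in the latter.

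Gratified ACTH mice were compared with control. In the hypothalamus Glul fell by 1.75 ± 0.11 (n = 6 against 4, limma adjusted p = 3.52e-10) and Alcam by 1.15 ± 0.11. Opalin, which fell, and Tagln2, which rose (adjusted p = 2.25e-15), are each tied on 4 of the 6 ACTH gratified arrays. Fos rose 1.32-fold (log2 0.40 ± 0.07, adjusted p = 0.000526) and Ier2 1.55-fold (log2 0.63 ± 0.07). Dbp, a clock-controlled transcription factor, fell by 0.65 ± 0.11. Hypothalamic neuropeptides fell for 7 of 28 (10 fell and 1 rose over the list alone), among them Trh, thyrotropin-releasing hormone (log2 -0.67 ± 0.14, adjusted p = 0.0035), while Hcrt did not pass (log2 -0.60 ± 0.26, adjusted p = 0.134, -0.27 without replicate 6, adjusted p = 0.0491 with array weights). Median over the list was -0.31 (adjusted p = 0.0027, adjusted p = 0.516 by estimated correlation). Cartpt, an appetite-suppressing peptide, fell by 0.54 ± 0.17 (adjusted p = 0.0418), and passed in only 2 of the 10 fits with 1 array left out (adjusted p up to 0.104). Microglia and macrophage members fell for 5 of 14 (7 over the list alone), with Cx3cr1 at -0.87 ± 0.11. The list median was -0.30 (adjusted p = 0.000188, adjusted p = 0.516 by estimated correlation). Oligodendrocyte and myelin members fell for 6 of 17 (7 over the list alone). Their median stood at -0.27 (adjusted p = 0.000385, adjusted p = 0.516 by estimated correlation). The striatum list fell for 2 of 18 (4 over the list alone, median -0.29, adjusted p = 0.0087). Thalamus and habenula markers fell for 4 of 11 (6 over the list alone, median -0.36, adjusted p = 0.0121) and glutamate receptors and postsynaptic density for 3 of 21 (4 over the list alone, median -0.18, adjusted p = 0.0287). For these 3 lists adjusted p = 0.516 by estimated correlation. Ppp1r1b did not pass (log2 -0.04 ± 0.10, adjusted p = 0.859).

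In that comparison 446 features rose and 761 fell, with series and treatment again not separable. With array medians set to 0, 273 rose and 979 fell, a share of rises of 21.8% in place of 37%. The count was 2840 with array weights, 498 with only the groups compared, 709, 736 and 743 without hypothalamus control replicates 1, 2 and 3, and 2445 without ACTH gratified replicate 4, the array farthest from its group. Without that array the hypothalamic neuropeptides (adjusted p = 0.24), striatum (adjusted p = 0.24), thalamus and habenula (adjusted p = 0.21) and glutamate receptors and postsynaptic density (adjusted p = 0.36) calls were lost. The striatum call was also lost without control replicate 1 (adjusted p = 0.089), and the glutamate receptors and postsynaptic density call without control replicate 1 (adjusted p = 0.061) or 4 (adjusted p = 0.071). Under quantile normalization only the microglia and macrophage call of the 6 stayed, Trh missed the threshold (adjusted p = 0.054) and the glutamate receptors and postsynaptic density median was 0.01.

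In the brain, ACTH gratified against control gave 1101 rises and 2025 falls. Glul fell 2.83-fold (n = 5 against 4, limma adjusted p = 0.000172), Mef2c by 1.23 ± 0.27 and Opalin 2.29-fold. Tagln2 passed as a rise, tied on 5 of 5 ACTH gratified arrays. Oxidative phosphorylation members fell for 30 of 44 (35 over the list alone, median -0.39, adjusted p = 3.22e-08). Proteasome members fell for 16 of 27 (also 16 over the list alone, median -0.30, adjusted p = 0.0001) and microglia and macrophage members for 9 of 14 (also 9 over the list alone, median -0.53, adjusted p = 0.0014). Each list had adjusted p = 0.924 by estimated correlation. Series and treatment cannot be told apart here either.

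Gratification itself was tested as ACTH gratified against ACTH, groups of the same number series. In the hypothalamus 1 feature passed: Nfyc, a subunit of the CCAAT-binding factor NF-Y, rose 1.43-fold (log2 0.52 ± 0.08, n = 6 against 5, limma adjusted p = 0.0318), with 761 features at an unadjusted p under 0.05. Striatal markers were lower as a list (median log2 -0.29, 0 of 18 over all features and 5 over the list alone, adjusted p = 1.97e-07, adjusted p = 0.261 by estimated correlation). Rgs9, a striatal regulator of G-protein signalling, stood at -0.49 ± 0.14 (adjusted p = 0.34) and Ppp1r1b at -0.27 ± 0.09 (adjusted p = 0.408). The dopamine and DARPP-32 signalling list was lower (median -0.10, 0 of 26 over all features, 1 higher and 6 lower over the list alone, adjusted p = 0.0026, adjusted p = 0.261 by estimated correlation), and 9 of its measured members are shared with the striatum list. The microglia and macrophage list was lower (median -0.16, 0 of 14 over all features and 4 over the list alone, adjusted p = 3.1e-05, adjusted p = 0.261 by estimated correlation), with the complement gene C1qc at -0.33 ± 0.07 (adjusted p = 0.128). No member passed over all features or over the list alone in the hypothalamic neuropeptides (median -0.20, adjusted p = 0.000322, adjusted p = 0.352 by estimated correlation), the opioid and cannabinoid signalling list (median -0.11, adjusted p = 0.0196, adjusted p = 0.405 by estimated correlation) or the cortex and hippocampus list (median -0.08, adjusted p = 0.04, adjusted p = 0.779 by estimated correlation), which were lower. The same held for oxidative phosphorylation (median 0.14, adjusted p = 0.0025) and proteasome (median 0.12, adjusted p = 0.0125), which were higher, both with adjusted p = 0.787 by estimated correlation. Fos (log2 0.22 ± 0.06, adjusted p = 0.339), Sgk1 (log2 0.54 ± 0.17, adjusted p = 0.349), Cartpt (log2 -0.33 ± 0.16, adjusted p = 0.621) and Hcrt (log2 -0.36 ± 0.24, adjusted p = 0.712, -0.034 without gratified replicate 6) did not pass.

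Nfyc did not pass under quantile normalization (adjusted p = 0.095), with only the groups compared in the fit (adjusted p = 0.87) or without ACTH replicates 1, 2 and 4 and ACTH gratified replicates 5 and 6 (adjusted p = 0.066, 0.088, 0.105, 0.0665 and 0.0595). Without ACTH gratified replicate 4 the oxidative phosphorylation median turned to -0.08 (adjusted p = 0.0036) and the proteasome median to -0.02 (adjusted p = 0.51). Without it the hypothalamic neuropeptides (adjusted p = 0.099), opioid and cannabinoid signalling (adjusted p = 0.44) and cortex and hippocampus (adjusted p = 0.64) calls were lost. The opioid and cannabinoid signalling call was lost also without ACTH replicate 4 (adjusted p = 0.065), and the cortex and hippocampus call without ACTH replicates 1, 4 and 5 and ACTH gratified replicates 3 and 5 (adjusted p = 0.092, 0.065, 0.13, 0.19 and 0.11). Those latter calls were lost under quantile normalization as well (opioid and cannabinoid signalling adjusted p = 0.064, cortex and hippocampus adjusted p = 0.11). The count of features was 0 without ACTH replicate 2 or 4 or ACTH gratified replicate 6, 2 and 3 without ACTH replicates 1 and 5, and 4, 7 and 3 without ACTH gratified replicates 1, 2 and 3.

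In the brain, ACTH gratified against ACTH called 6 features with limma, all lower after gratification, and 0 lists. Adamts1, an extracellular protease, fell 2.28-fold (log2 -1.19 ± 0.15, n = 5 against 4, adjusted p = 0.000732). Ncaph, a condensin subunit, fell by 0.83 ± 0.14, the cyclin Ccne2 by 0.78 ± 0.11, Gas2, a cytoskeletal protein, by 0.67 ± 0.09, and Akip1 by 0.57 ± 0.10 (adjusted p = 0.035). Met, the hepatocyte growth factor receptor, passed too, tied on 4 of 4 ACTH arrays. These 6 were also called with the opposite sign in ACTH against control, comparisons that share the ACTH arrays. Simulated unchanged groups gave 0.88 such features, and ACTH arrays split between the comparisons 2 to 14, with 0 to 11 of the same sign. The covariance of effects was -0.012, simulated -0.0095, and with the split -0.0008 (-0.0068 to 0.0106). With only the groups compared in the fit 1 feature passed, and the adjusted p of Adamts1 was 0.17, of Ccne2 0.15 and of Gas2 0.15. Akip1 was also lost without each of ACTH gratified replicates 1, 3, 4 and 5 (adjusted p = 0.07, 0.08, 0.07 and 0.12). The count was 22 with array weights and 41, 17 and 21 without ACTH replicates 1, 2 and 4.

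Furosemide was compared with control in the hypothalamus. As a group, striatal markers were higher: 17 of 18 lay above 0 (median log2 0.34, 0 over all features and 1, Drd1, over the list alone, limma's camera adjusted p = 1.12e-08, adjusted p = 0.316 by estimated correlation). Of the dopamine receptors, Drd1 stood at 0.58 ± 0.15 (n = 4 and 4, adjusted p = 0.607) and Drd2 at 0.41 ± 0.14 (adjusted p = 0.607). All 13 choroid plexus and ependyma markers lay above 0 (median 0.28, 0 over all features and 1, Folr1, over the list alone, adjusted p = 7.52e-06, adjusted p = 0.316 by estimated correlation). Folr1, a folate receptor, stood at 0.50 ± 0.12 (adjusted p = 0.579). Glucocorticoid-responsive genes were higher as a list (median 0.15, 14 of 18 above 0, 0 over all features and 3 over the list alone, adjusted p = 0.003, adjusted p = 0.316 by estimated correlation). Among them were Sgk1, a kinase induced by corticosteroids that raises renal sodium uptake, at 0.66 ± 0.19 (adjusted p = 0.607) and the NF-kappaB inhibitor Nfkbia at 0.38 ± 0.12 (adjusted p = 0.607).

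The dopamine and DARPP-32 signalling list was higher (median 0.17, 19 of 26 above 0, 0 over all features and 1, Drd1, over the list alone, adjusted p = 0.003, adjusted p = 0.316 by estimated correlation). Oxidative phosphorylation was higher as well (median 0.12, 43 of 44 above 0, 0 over all features and 0 over the list alone, adjusted p = 0.0363, adjusted p = 0.898 by estimated correlation). Ppp1r1b (log2 0.25 ± 0.11, adjusted p = 0.733), Arc (log2 0.25 ± 0.14, adjusted p = 0.902), Fos (log2 -0.04 ± 0.07), Cartpt (log2 0.01 ± 0.19) and Hcrt (log2 -0.03 ± 0.29) did not pass. Neither did the kinase Lrrk2 (feature LRRK2g-s1, log2 0.57 ± 0.11, adjusted p = 0.101). Over all features limma called 2, both lower, and 582 lay at an unadjusted p under 0.05: Rlbp1, a retinaldehyde-binding protein (adjusted p = 0.0366), and OR2A5gs (log2 -0.56 ± 0.10, adjusted p = 0.0454), a feature without a mouse symbol. Rlbp1 had tied values on 60.9% of the hypothalamus arrays. The count was 0 without hypothalamus control replicate 1, 2, 3 or 4 or furosemide replicate 1 or 2 and 1 without furosemide replicate 4, 40 with array weights and 0 without tied features, with array medians set to 0 or with only the groups compared. Without control replicate 2 the dopamine and DARPP-32 signalling call was lost (adjusted p = 0.066), and oxidative phosphorylation was lost without control replicates 2 and 4 and furosemide replicates 1 and 4 (adjusted p = 0.066, 0.21, 0.10 and 0.071).

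**Figure D3:**
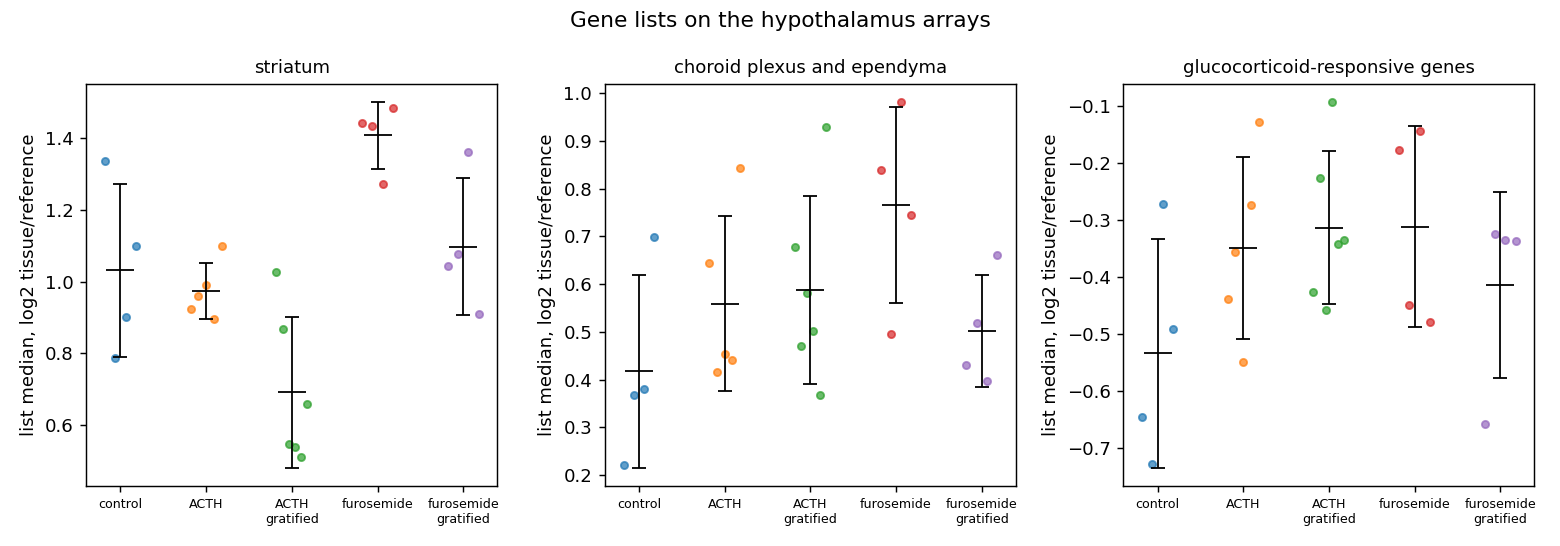
Median log2 ratio of the striatum, choroid plexus and ependyma, and glucocorticoid-responsive lists on each hypothalamus array, by group. Points are arrays, bars the group means and error bars the SD. Against control, the median member of the striatum list stood 0.34 higher in the furosemide group, and in the furosemide gratified group 0.23 lower than in the furosemide group.

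In the brain, 9 features rose with furosemide and 0 fell (1174 at an unadjusted p under 0.05 by limma). Myh11 (feature MYH11g-s3), smooth muscle myosin, rose 1.74-fold (log2 0.80 ± 0.15, n = 4 and 4, adjusted p = 0.0327), the adhesion protein Cadm4 1.71-fold (log2 0.78 ± 0.14). Olig2 (feature OLIG2g-s2), a transcription factor of the oligodendrocyte lineage, rose 1.56-fold (log2 0.65 ± 0.12), and the postsynaptic scaffold Shank3 (feature SHANK3g-s2) 1.49-fold (log2 0.58 ± 0.10). The other feature of Shank3 did not pass. Hnrnpul1 (feature HNRNPUL1g-s2), Traf3ip3 and Cflar (feature CFLARg-s2) passed as rises, with tied values on over 70% of the brain arrays. The chemokine receptor Ccr4 rose by 0.47 ± 0.09. The oligodendrocyte and myelin list was higher, with 16 of 17 above 0 (median log2 0.25, 0 over all features and 6 over the list alone, adjusted p = 2.17e-08, adjusted p = 0.447 by estimated correlation). Examples are the connexin Gjc3 (0.36 ± 0.08, adjusted p = 0.132) and the myelin gene Mobp (feature MOBPg-s2, 0.49 ± 0.12, adjusted p = 0.172). All 13 choroid plexus and ependyma markers lay above 0 (median 0.33, 0 over all features and 0 over the list alone, adjusted p = 0.000268, adjusted p = 0.447 by estimated correlation), with Ttr, transthyretin, at 1.09 ± 0.44 (adjusted p = 0.325). Sgk1 stood at 0.64 ± 0.17 (adjusted p = 0.176). Each of the 8 named features was lost in 6 or 7 of the 8 fits with 1 array left out. The count was 182 with array weights, 4 with only the groups compared and 0 under quantile normalization, with the block or without tied features. It was 71, 17, 3 and 0 without brain control replicates 1, 2, 3 and 4, and 1, 1, 0 and 0 without furosemide replicates 1, 2, 3 and 4. Gjc3 (adjusted p = 0.0087) and Mobp (adjusted p = 0.022) passed without control replicate 1.

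For furosemide, the effects of the tissues correlated with r = -0.22 across features, and the test of the difference called 6 features (limma, 1084 at an unadjusted p under 0.05). Mtmr1 (feature MTMR1g-s1), a phosphoinositide phosphatase, was higher in hypothalamus relative to brain by a log2 of 0.70 ± 0.14 (adjusted p = 0.0314). Ccr4 (log2 -0.71 ± 0.13, adjusted p = 0.0154) and OR2A5gs (log2 -0.84 ± 0.14, adjusted p = 0.0058) were lower, as were Hnrnpul1 (adjusted p = 0.0134) and Rlbp1 (adjusted p = 0.0219), tied on 3 of 4 hypothalamus control arrays. The striatum list was higher in hypothalamus relative to brain (median 0.34, 0 over all features and 2 over the list alone, adjusted p = 0.0101). So were oxidative phosphorylation (median 0.22, 0 and 0 over the list alone, adjusted p = 0.0138) and microglia and macrophage (median 0.27, 0 and 2 over the list alone, adjusted p = 0.031), while oligodendrocyte and myelin was lower (median -0.17, 0 and 1 over the list alone, adjusted p = 0.00027). These 4 lists had adjusted p = 0.922 by estimated correlation. The controls and furosemide arrays of the tissues are in different number series. The count was 507 with array weights, 48, 16, 14, 10 and 11 without brain control replicates 1 and 2, brain furosemide replicate 3, hypothalamus control replicate 1 and hypothalamus furosemide replicate 4, and 1 without hypothalamus control replicate 4 or without tied features. It was 2 without brain control replicate 3 or hypothalamus control replicate 2, and 3 without hypothalamus furosemide replicate 2 or 3. Mtmr1 passed in 7 of 16 fits with 1 array left out (adjusted p up to 0.127). The striatum call was lost without brain furosemide replicate 1 (adjusted p = 0.18) and hypothalamus control replicates 2 and 3 (adjusted p = 0.12 and 0.053). Oxidative phosphorylation was lost without brain control replicates 1 and 3 (adjusted p = 0.06 and 0.13). Microglia and macrophage was lost without those (adjusted p = 0.063 and 0.16), brain furosemide replicate 1 (adjusted p = 0.11) and hypothalamus control replicates 2 and 3 (adjusted p = 0.09 and 0.11).

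After gratification, 3 of the lists that were higher with furosemide in the hypothalamus were lower than with furosemide alone. All 13 choroid plexus and ependyma markers lay below 0 (median log2 -0.36, 0 over all features and 5 over the list alone, limma's camera adjusted p = 2.24e-11, adjusted p = 0.21 by estimated correlation). The chloride channel protein Clic6 stood at -0.39 ± 0.12 (n = 4 and 4, adjusted p = 0.974), and Folr1 (adjusted p = 0.333) is tied on 3 of 4 furosemide gratified arrays. Of 18 striatum members 17 lay below 0 (median -0.23, 0 over all features and 2, Penk and Drd1, over the list alone, adjusted p = 2.31e-08, adjusted p = 0.234 by estimated correlation). Penk, the enkephalin precursor, stood at -0.88 ± 0.25 (adjusted p = 0.791, -0.56 without gratified replicate 4) and Drd1 at -0.49 ± 0.15 (adjusted p = 0.992). Glucocorticoid-responsive genes were lower (median -0.16, 0 over all features and 1, Gpd1, over the list alone, adjusted p = 0.000136, adjusted p = 0.228 by estimated correlation), with Sgk1 at -0.57 ± 0.19. These comparisons share the furosemide arrays: the covariance of the effects over all features was -0.0107, the simulated value was also -0.0107, and with the arrays split it was -0.0066.

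Over all features limma called 1, C20orf57g-s2 (log2 -0.50 ± 0.07, adjusted p = 0.0015), which has no mouse symbol, and 316 lay at an unadjusted p under 0.05. Slc1a2 (feature SLC1A2g-s1), the astrocytic glutamate transporter, stood at -1.07 ± 0.21 (adjusted p = 0.214) and Fabp5 at 1.02 ± 0.24 (adjusted p = 0.333). Gratified arrays span a pair of number series. In the 2-digit arrays alone 27 features passed, with the series as a factor 33. Under both, the same comparison of gratified replicates 3 and 4, Slc1a2 (adjusted p up to 1.2e-05) and Penk (adjusted p up to 9.5e-05) passed. The glucocorticoid-responsive genes call was lost with the factor (median -0.11, adjusted p = 0.081). The count was 10 with array weights, 7 without gratified replicate 2, when Slc1a2 passed (adjusted p = 9.9e-06), 2 without furosemide replicate 4 or gratified replicate 3, when Fabp5 passed (adjusted p = 0.0042), and C20orf57g-s2 was lost under quantile normalization (adjusted p = 0.23).

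In the brain, furosemide gratified against furosemide called 0 features with limma (344 at an unadjusted p under 0.05). Glucocorticoid-responsive genes were lower as a list (median log2 -0.17, 0 of 18 over all features and 4 over the list alone, adjusted p = 3.6e-06, adjusted p = 0.154 by estimated correlation). Sgk1 stood at -0.58 ± 0.17 (n = 4 and 4, adjusted p = 0.999) and the kinase Map3k6 at -0.30 ± 0.09 (adjusted p = 0.999). Hnrnpul1, among the rises with furosemide, stood at -0.48 ± 0.10 (adjusted p = 0.783).

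Furosemide gratified against control in the hypothalamus called 0 features with limma (282 at an unadjusted p under 0.05). The largest differences by the naming rule were Mid1, a ubiquitin ligase (log2 -1.64 ± 0.39, n = 4 and 4, adjusted p = 0.888), Slc1a2 (-0.77 ± 0.21) and Per3, a clock gene (1.00 ± 0.35, 0.46 without gratified replicate 4). The dopamine and DARPP-32 signalling list was higher (median 0.10, 0 over all features and 0 over the list alone, adjusted p = 0.0316, adjusted p = 0.973 by estimated correlation). That call was lost without control replicates 2, 3 and 4 and furosemide gratified replicates 1, 3 and 4 (adjusted p = 0.50, 0.13, 0.053, 0.17, 0.075 and 0.076). In the 2-digit arrays alone 20 features passed, with the series as a factor (same comparison) 21, Slc1a2 (adjusted p up to 0.00029) and Per3 (adjusted p up to 0.0016) among them.

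In the brain this called 0 features with limma, although 1827 lay at an unadjusted p under 0.05. Ascc2 (feature ASCC2g-s1), Lmbr1 (feature LMBR1g-s1) and Med24, a Mediator subunit, came closest (log2 -0.49 ± 0.09, 0.40 ± 0.07 and -0.74 ± 0.14, n = 4 and 4, adjusted p = 0.0669 each). The oligodendrocyte and myelin list was higher (median 0.19, 0 over all features and 2 over the list alone, adjusted p = 0.000896). Higher too were choroid plexus and ependyma (median 0.28, 0 and 0 over the list alone, adjusted p = 0.0035) and cerebellum (median 0.35, 0 and 0 over the list alone, adjusted p = 0.0232). Oxidative phosphorylation (median -0.15, 0 and 1 over the list alone, adjusted p = 0.0074) and microglia and macrophage (median -0.21, 0 and 3 over the list alone, adjusted p = 0.034) were lower, and all 5 lists had adjusted p = 0.891 by estimated correlation. With the number series as a factor, only furosemide gratified replicate 1, the zero-padded array of its group, is set against the controls. The medians were then 0.02 for oligodendrocyte and myelin and -0.09 for choroid plexus and ependyma. Resting on 1 array, they do not decide whether the series matters. Without furosemide gratified replicate 4 the cerebellum median was -0.01 (adjusted p = 0.54) and microglia and macrophage had adjusted p = 0.28. Without brain control replicate 1, 446 features passed, Ascc2 and Med24 among them (adjusted p = 0.0011 each). Without it the cerebellum (adjusted p = 0.086), oxidative phosphorylation (adjusted p = 0.073) and microglia and macrophage (adjusted p = 0.094) calls were lost. Without control replicate 3 the latter 2 were lost (adjusted p = 0.24 each), oxidative phosphorylation also without furosemide gratified replicates 1 and 2 (adjusted p = 0.059 and 0.54). The count was 72 and 100 without furosemide gratified replicates 1 and 3, 1 without replicates 2 or 4 and 4 without control replicate 2.

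ACTH and furosemide groups were compared directly. In the hypothalamus 886 features were higher and 1282 lower with ACTH. Glul was lower (log2 -1.64 ± 0.11, n = 5 against 4, limma adjusted p = 3.13e-09), as was the phosphatase Ptpn4 (log2 -1.59 ± 0.30). Tagln2 (adjusted p = 1.8e-15) and Fabp5, a fatty acid-binding protein, passed as higher, both tied on 5 of 5 ACTH arrays, and Fos was higher by a log2 of 0.22 ± 0.07 (adjusted p = 0.0292). In the oxidative phosphorylation list 14 of 44 were lower and 1 higher (23 and 1 over the list alone, median -0.39, adjusted p = 6.5e-05). In the proteasome list 7 of 27 were lower (10 over the list alone, median -0.31, adjusted p = 0.0025). For oligodendrocyte and myelin 6 of 17 were lower (8 over the list alone, median -0.28, adjusted p = 0.0051) and in the striatum list 5 of 18 lower (also 5 over the list alone, median -0.31, adjusted p = 0.0214). All 4 lists had adjusted p = 0.583 by estimated correlation. Series and treatment cannot be told apart, and under quantile normalization the oligodendrocyte and myelin (adjusted p = 0.29) and striatum (adjusted p = 0.27) calls were lost. The count was 4516 with array weights, 3762 with only the groups compared and 1328 without furosemide replicate 1, and Fos was lost without ACTH replicates 1 and 4 and furosemide replicates 1, 2 and 3 (adjusted p = 0.065, 0.072, 0.058, 0.078 and 0.085).

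In the brain 497 features were higher and 1042 lower with ACTH than with furosemide. Adamts1 was 2.39-fold higher (log2 1.26 ± 0.16, n = 4 and 4, limma adjusted p = 0.000122), and Tagln2 passed as higher (adjusted p = 3.49e-15), tied on 4 of 4 ACTH arrays, while Glul and the semaphorin Sema7a were lower (log2 -1.60 ± 0.25 and -1.12 ± 0.10). Opalin passed as lower, tied on 3 of 4 ACTH arrays. Of 17 oligodendrocyte and myelin members 11 were lower (13 over the list alone). For the list, the median was -0.53 (adjusted p = 2.27e-10, adjusted p = 0.343 by estimated correlation). Oxidative phosphorylation was lower for 19 of 44 (27 over the list alone, median -0.32, adjusted p = 1.29e-07). Proteasome members were lower for 10 of 27 (15 lower and 1 higher over the list alone, median -0.26, adjusted p = 3.05e-05). Lower too were GABA synthesis, transport and receptors for 4 of 14 (5 over the list alone, median -0.30, adjusted p = 0.0317), neuron for 3 of 16 (also 3 over the list alone, median -0.28, adjusted p = 0.0485) and microglia and macrophage for 5 of 14 (8 over the list alone, median -0.32, adjusted p = 0.0485). Each of these lists had adjusted p = 0.601 by estimated correlation. Proliferation genes were higher for 4 of 20 (5 over the list alone). The median over the list was 0.10 (adjusted p = 0.0185, adjusted p = 0.343 by estimated correlation). Series and treatment cannot be told apart, and under quantile normalization GABA synthesis, transport and receptors (median -0.03, adjusted p = 0.97), neuron (median -0.04, adjusted p = 0.83) and microglia and macrophage (adjusted p = 0.11) were not called. Without ACTH replicate 4 the count was 772 and those 3 lists (adjusted p = 0.14, 0.18 and 0.14) and proliferation (adjusted p = 0.051) were lost. The count was 2503 with array weights and 853, 804 and 981 without furosemide replicates 2, 3 and 4. Neuron was lost without furosemide replicates 1 and 2 (adjusted p = 0.11 and 0.052), and microglia and macrophage without ACTH replicate 1 and furosemide replicates 2 and 4 (adjusted p = 0.062, 0.059 and 0.068).

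Effects against the shared controls were also compared between treatments. In the hypothalamus the ACTH and furosemide effects correlated with r = -0.05 across features, with a covariance of -0.0016 against 0.0102 in simulated unchanged groups sharing those controls, and -0.0087 with the controls split. The features called in both numbered 0. In the brain r was 0.56, the covariance 0.0279 against a simulated 0.0095, and 0.0196 with the controls split. There, 7 of the 9 features that rose with furosemide also rose with ACTH, against 0 in simulated groups and 0.837 in independent lists. With split controls 0 to 15 shared the sign and 0 to 6 did not.

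Several lists were called in 0 of the 17 comparisons by limma's camera. The renin-angiotensin, corticosteroid and natriuretic peptide systems list had medians from -0.12 to 0.06 and a smallest adjusted p of 0.074, and the sodium channels and sodium-coupled transporters list medians from -0.20 to 0.11 and a smallest adjusted p of 0.0885. For MAPK and CREB signalling, heat shock and endoplasmic reticulum stress, cytosolic ribosomal proteins and circadian clock the smallest adjusted p was 0.229, 0.065, 0.125 and 0.235. For the astrocyte, endothelium and mural cells, and blood lists it was 0.174, 0.0561 and 0.0509.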

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

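The tests of the ACTH arrays (correlation between tissues, tied shares and the glucocorticoid list), that of oxidative phosphorylation on 1 array and the divisions of arrays for lists other than striatum were chosen only after the result was seen, and the others before.

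Features that differ between ACTH and control arrays were the largest pattern. Few falls lay at a floor of weak spots, since features tied on most high-number arrays made up 1.39% of the falls in hypothalamus and 1.82% in brain, against 20.6 and 23.7% of the features that did not pass. The rises fit such a floor (53.1 and 56%). Its indirect effects on falls were not tested. Whether the falls come from ACTH or from the number series stays open: all ACTH arrays are in 1 series, and the correlation of the effects between tissues, 0.71, would arise from either. The median of the glucocorticoid-responsive genes, 0.077 in hypothalamus, leaves a response to adrenal steroids open too.

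The striatum list was higher in the hypothalamus with furosemide, where 1 of 35 splits, the real one, reached the median of 0.34 (highest other 0.29). It had the smallest list p, so chance stays open. The number series as a factor left 0.34, which decides nothing, as all 8 arrays are in 1 series. Striatum members outside the dopamine list had a median of 0.32 (8 of 9 above 0), which 17 of 18 above 0 in the whole list already fixes, so more neighbouring striatal tissue with furosemide stays open. The list's residual correlation, 0.344, lay above 10000 random lists (highest 0.316). The lists had -0.015 to 0.76 (oxidative phosphorylation), so this decides nothing. A response of dopamine signalling genes stays open too, as dopamine members outside the striatum list had a median of 0.087 (10 of 17 above 0, exact sign test p = 0.629).

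Hypothalamus ACTH gratified replicate 4 stood apart from its group. Its slope against the other arrays of the group was 0.725 (others 1.02 to 1.04). Both compressed ratios and a low correlation lower a slope, so this does not tell them apart. Compression alone is argued against by the oxidative phosphorylation median of 0.77 on this array, with -0.44 to -0.23 on the others, as it cannot turn the sign. Another mix of brain regions stays open, with 2 of 7 regional lists farther from their group than on any other hypothalamus array. Its median ratio was -0.05 (others -0.221 to -0.167), its SD 0.669 (0.743 to 0.747) and its mean correlation with the group 0.77 (0.903 to 0.915). Further values on it were Tagln2 0.071, and list medians of renin-angiotensin, corticosteroid and natriuretic peptide systems 0.22, opioid and cannabinoid signalling 0.27, proteasome -0.11, cytosolic ribosomal proteins -0.35, heat shock and endoplasmic reticulum stress -0.10 and proliferation -1.11.

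Chance divisions of the arrays were tried for each count of called features. The real division gave the highest count, 1 of the splits tried, for ACTH against control (1005, highest other 309) and against furosemide (2168, other 1067) in hypothalamus, for ACTH against control (2868, other 97), ACTH gratified against control (3126, other 1736) and ACTH against furosemide (1539, other 6) in brain, and for the controls of the tissues (269, other 17). It also did for furosemide against control in hypothalamus (2, other 1) and brain (9, other 5) and for the tissue difference of furosemide (6, other 3), where the margins are small. For ACTH gratified against control in hypothalamus 3 of 100 splits reached 1207 (highest other 2137, with control replicate 4 and ACTH gratified replicate 4 exchanged). Chance cannot be excluded for ACTH gratified against ACTH in hypothalamus (58 of 100, real count 1, other 14) and brain (8 of 100, real count 6, other 35) or for furosemide gratified against furosemide in hypothalamus (5 of 35, real count 1, other 2). Where 0 features passed every split reaches that count, which decides nothing: furosemide gratified against furosemide in brain (35 of 35, other 2) and against control in hypothalamus (35, other 8) and brain (35, other 197), and the tissue difference of ACTH (100 of 100, other 1797, as swapping labels in 1 tissue adds the effects).

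Of 59 lists picked as called between a pair of groups, 38 had fewer than 1 in 20 splits as far from 0 as the real median. For 21 the splits do not exclude chance. In hypothalamus these were, for ACTH gratified against ACTH, oxidative phosphorylation (414 of 462 splits, real distance 0.14, highest other 0.36), proteasome (297, 0.12, other 0.21), cortex and hippocampus (239, 0.082, other 0.35), opioid and cannabinoid signalling (69, 0.11, other 0.16) and dopamine and DARPP-32 signalling (52, 0.10, other 0.16). For furosemide they were choroid plexus and ependyma (3 of 35, 0.28, other 0.45) and oxidative phosphorylation (2, 0.116, other 0.117), and after its gratification choroid plexus and ependyma (2, 0.363, other 0.364) and, against control, dopamine and DARPP-32 signalling (4, 0.10, other 0.14). They were also oligodendrocyte and myelin for ACTH (7 of 126, 0.27, other 0.33) and, for ACTH gratified against control, glutamate receptors and postsynaptic density (14 of 210, 0.18, other 0.28) and striatum (14, 0.29, other 0.40). In brain they were, for furosemide, choroid plexus and ependyma (3 of 35, 0.33, other 0.44) and oligodendrocyte and myelin (3, 0.25, other 0.27). For furosemide gratified against control they were oxidative phosphorylation (13, 0.15, other 0.30), choroid plexus and ependyma (11, 0.28, other 0.72), cerebellum (6, 0.353, other 0.375), oligodendrocyte and myelin (5, 0.19, other 0.26) and microglia and macrophage (4, 0.21, other 0.29). Between the control tissues they were oligodendrocyte and myelin (2, 0.25, other 0.28) and pituitary (2, 0.28, other 0.31).

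Values of single arrays stood apart from the others of their group in 62 of 635 groups tested, where chance gives about 1 in 20. Array medians did so for brain control replicate 1 (-0.229, others -0.165 to -0.156), brain furosemide replicate 1 (-0.179), brain furosemide gratified replicate 4 (-0.243) and hypothalamus furosemide gratified replicate 1 (-0.157). Brain ACTH gratified replicate 5 had 27.1% tied values (others 22.4 to 23.3%), and hypothalamus control replicate 4 a mean correlation of 0.936 (others 0.955 to 0.957). Among genes in hypothalamus these were, in control replicate 4, Glul 1.29 (others 1.67 to 1.75), Syn2 1.12 and Trem2 -0.70, and in control replicate 1 Lcn2 -1.23 and Drd1 1.32 (others 0.79 to 0.80). In ACTH arrays they were Serpinb13 -0.14 and Il17f -0.36 (replicate 5), Jund -0.28 and Tcf7l2 -0.14 (replicate 3) and C1qc 1.80 (replicate 4). Hcrt stood at 0.34 in ACTH gratified replicate 6 (others 2.08 to 2.66), and Glul at 1.13 in furosemide replicate 3. In brain controls they were Traf3ip3 -0.18, Med24 0.13 and Rgs16 0.53 (replicate 1), Cox8a 0.012 and Tsc22d3 -0.064 (replicate 2) and Egr1 -0.74 (replicate 4). In brain ACTH arrays they were Alcam -0.34 (replicate 3) and Akip1 0.40 (replicate 2), and in ACTH gratified replicate 1 Adamts1 -0.64 (others -1.56 to -1.40).

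List medians over 1 feature per gene standing apart in hypothalamus were hypothalamic neuropeptides 1.11 (ACTH replicate 1), GABA synthesis, transport and receptors 1.08 and neuron 1.10 (ACTH replicate 3), neuron 1.76 (furosemide replicate 4), microglia and macrophage 0.075 (furosemide replicate 2), glucocorticoid-responsive genes -0.66 (furosemide gratified replicate 1) and oligodendrocyte and myelin 2.17 (furosemide gratified replicate 2). In brain the cerebellum list did so most, at 0.53 in control replicate 2, 1.63 in ACTH gratified replicate 3 (others 0.50 to 0.72), 1.63 in furosemide replicate 1 (others 0.62 to 0.79) and 2.03 in furosemide gratified replicate 4 (others 0.63 to 0.86). Furosemide replicate 1 also had cortex and hippocampus 1.04, oligodendrocyte and myelin 1.97 and renin-angiotensin, corticosteroid and natriuretic peptide systems 0.42, a list at 0.56 in ACTH replicate 1 and 0.55 in ACTH gratified replicate 2. Others were MAPK and CREB signalling -0.29 (control replicate 3), endothelium and mural cells 0.24 (control replicate 1), circadian clock -0.092 (ACTH replicate 1) and -0.14 (furosemide gratified replicate 4), GABA synthesis, transport and receptors 1.18 and oxidative phosphorylation -0.21 (ACTH gratified replicate 3), blood 0.0295 (ACTH gratified replicate 4) and preoptic and hypothalamic regional markers 0.57 (furosemide replicate 2).

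Between groups, the furosemide effect differed between tissues for 6 features, among them Mtmr1 0.70, Ccr4 -0.71, OR2A5gs -0.84 and, tied on 3 of 4 hypothalamus control arrays, Hnrnpul1 -0.93 and Rlbp1 -0.70, no exact sizes.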

How the results depend on the processing

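Alternatives that left out tied features, replaced controls by ACTH arrays, or repeated list tests with 1 array left out, a block, the series or without tied features, or paired neighbouring numbers were chosen only after the result was seen.

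Of the results for named genes, 152 kept their call under quantile normalization, 19 lost it and 5 gained one, with array medians set to 0 171 kept, 4 lost and 1 gained it, and with the block 160 kept and 16 lost it. Array weights kept 163, lost 0 and gained 13, a trended robust variance kept 175 and lost 1, and the fit with only the compared groups kept 148, lost 26 and gained 2. Lists kept 51 calls and lost 11 under quantile normalization, with 3 reversed. The mean of all features kept 64 and lost 1, and an estimated correlation kept 4 and lost 61. With 1 array left out, 1411 gene results stayed, 136 were lost and 25 were gained, and 557 list results stayed, 58 were lost and 2 reversed. With ACTH and ACTH gratified arrays in place of controls, 268 features differed between tissues, against 269. The filter for values on every array has no separate value, as none are missing, and ACTH against control or furosemide could not be fitted with the series.

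With array weights the counts in hypothalamus were ACTH against control 2753, furosemide against control 40, ACTH gratified against ACTH 2, furosemide gratified against furosemide 10, ACTH gratified against control 2840 and ACTH against furosemide 4516. In brain they were furosemide against control 182, ACTH gratified against ACTH 22, furosemide gratified against furosemide 3 and against control 2, and ACTH against furosemide 2503. For the controls of the tissues the count was 624, and for the tissue differences of ACTH and furosemide 1 and 507. With only the groups of a comparison the counts in hypothalamus were ACTH against control 1698, furosemide against control 0, ACTH gratified against ACTH 0, furosemide gratified against furosemide 2, ACTH gratified against control 498, furosemide gratified against control 1 and ACTH against furosemide 3762. In brain they were 4 for furosemide, 1 for ACTH gratified against ACTH and 1 for furosemide gratified against furosemide, and for the tissue difference of furosemide 2.

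Under quantile normalization the counts were 1 for furosemide, 0 for ACTH gratified against ACTH and 0 for furosemide gratified against furosemide in hypothalamus, 0 for furosemide and 9 for furosemide gratified against control in brain, and 11 for the tissue difference of furosemide. With array medians set to 0, furosemide in hypothalamus gave 0 and furosemide gratified against control in brain 1. The share of rises in the tissue difference of furosemide was 33.3%, with quantile normalization 18.2% and with medians set to 0 20%. A trended robust variance gave 10 for ACTH gratified against ACTH in brain. Without tied features furosemide gave 0 in hypothalamus, 0 in brain and 1 for the tissue difference. With the number series as a factor furosemide in hypothalamus gave 0, furosemide gratified against furosemide 33 and against control 21, the controls of the tissues 34 and the tissue difference of furosemide 11. In the 2-digit series alone furosemide gratified gave 27 against furosemide and 20 against control. Series alone called 22 features in hypothalamus and 0 in brain among arrays without ACTH.

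With 1 array left out, counts in hypothalamus ranged from 514 to 1063 for ACTH, 0 to 2 for furosemide, 0 to 7 for ACTH gratified against ACTH, 1 to 7 for furosemide gratified against furosemide, 709 to 2445 for ACTH gratified against control, 0 to 4 for furosemide gratified against control and 1328 to 2060 for ACTH against furosemide. In brain, in the same order, they ranged from 1895 to 2979, 0 to 71, 5 to 41, 0 to 1, 2104 to 3189, 0 to 446 and 772 to 1469. They ranged from 169 to 341 for the controls of the tissues, 0 to 2 for the tissue difference of ACTH and 1 to 48 for that of furosemide. Counts of lists in hypothalamus ranged from 3 to 8 for furosemide, 4 to 12 for ACTH gratified against ACTH, 3 to 7 for furosemide gratified against furosemide and 0 to 3 against control. In brain they ranged from 3 to 5 for ACTH, 3 to 6 for furosemide, 0 to 2 for ACTH gratified against ACTH, 1 to 6 for furosemide gratified against furosemide, 2 to 6 against control and 3 to 9 for ACTH against furosemide, and for the tissue differences from 1 to 6 and 2 to 6. Oxidative phosphorylation in ACTH gratified against ACTH ranged from -0.076 to 0.19 and proteasome from -0.023 to 0.15.

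With an estimated correlation 4 lists were called between the control tissues and 0 in every other comparison. By the rotation test fry, 6 lists were called for ACTH against control in hypothalamus and 8 between the control tissues, and 13, 16, 7, 9 and 12 for ACTH gratified against control and ACTH against furosemide in hypothalamus, and ACTH against control, ACTH gratified against control and ACTH against furosemide in brain. In both tissues fry called 0 for furosemide against control, for ACTH gratified against ACTH and for furosemide gratified against furosemide or control, and it called 0 for both tissue differences. Quantile normalization gave 1 list for ACTH gratified against control, 2 for furosemide gratified against control and 2 for ACTH against furosemide in hypothalamus, 5 for furosemide and 4 for ACTH against furosemide in brain, and 1 for the tissue difference of ACTH. Under it the glutamate receptors and postsynaptic density median of ACTH gratified against control was 0.012, and for ACTH against furosemide in brain that of GABA synthesis, transport and receptors was -0.032 and that of neuron -0.039. Without tied features 0 lists were called for furosemide gratified against control in hypothalamus, and in brain 8 for furosemide, 2 for furosemide gratified against furosemide and 4 for ACTH against furosemide. With the series, 0 lists were called for furosemide gratified against control in hypothalamus, 4 for furosemide gratified against furosemide and 1 against control in brain, 11 between control tissues and 1 for the tissue difference of ACTH, and choroid plexus and ependyma stood at -0.092 for furosemide gratified against control in brain. The mean of all features gave 6 lists for furosemide in brain, and the striatum list for ACTH against furosemide in hypothalamus was then not called (adjusted p = 0.055).

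Replicate numbers do not pair the arrays: residuals of equal numbers correlated at 0.0094 in hypothalamus and -0.0023 in brain, and at 0.0398 between tissues. Residuals of 10 pairs of hypothalamus and brain arrays of a treatment with neighbouring description numbers correlated at 0.0678 (-0.045 to 0.20), and other pairs at -0.0071 (-0.25 to 0.20), so whether those share an animal stays open. With these as pairs 271 features differed between the control tissues, 0 for the tissue difference of ACTH and 6 for that of furosemide, against 269, 0 and 6. As a block the replicate numbers gave 0 for furosemide, 0 for ACTH gratified against ACTH and 797 for ACTH gratified against control in hypothalamus, and 0 for furosemide in brain.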
